A study of Mus musculus with 8 samples.

How the data were processed

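Per the labels' protocols, ganglia were incubated in a collagenase and dispase mixture and dissociated, fluorescent neurons were picked by hand, and each picking session included 1 sample per genotype. RNA was extracted from each pool with a PicoPure kit, cDNA was amplified with the Ovation RNA-seq System V2 and libraries were made with Nextera XT. The samples came from mice of both sexes at 3 to 5 weeks of age. Cells were pooled before extraction, so a library gives the mean of its cells. Amplification from small pools adds spread, above all to genes of low abundance.

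The authors deposited 1 table of raw counts, whole numbers of reads per gene symbol, with 1 column for each of the 8 samples. Per the submitters' processing notes, reads were handled with bcl2fastq 2.17 and Trimmomatic 0.33 and counted with featureCounts on the mouse genome build GRCm38. The aligner, the gene annotation, the use of strand and the treatment of reads with several matches are not given in the sources used here. Columns were matched to samples by name, and 0 columns were left unused. The table held 43372 gene symbols, of which 21959 had at least 1 count. For coordinates, lengths and GC content, symbols were looked up in the GENCODE M21 annotation of GRCm38, where 39469 of all symbols and 11258 of the 11828 tested were found. Genes with near-identical copies, such as the Mrgpr family, Calca and Calcb, the alpha globins and mitochondrial genes with nuclear copies, can share or lose reads in counting and are uncertain.

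The deposited counts were tested as they stood. Library totals were scaled by the trimmed mean of M-values (TMM), and genes were kept with the expression filter of edgeR at its minimum count of 10, which left 11828. The groups were compared with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood F test with robust dispersion estimates and group as the sole term, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are Sst over Trpv1, so a negative value means lower in the Sst libraries. Standard errors were derived from the fold change and the F statistic. CPM values are TMM-normalized, and log2 CPM used a prior count of 2. The biological coefficient of variation was 69.1%, and the median log2 fold change over all genes 0.01. No 2 libraries of a group were alike within counting error: over the 12 pairs within groups the chi-square statistic per degree of freedom ran from 43.4 to 108.

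Gene lists of neuron classes, receptors, channels, peptides and other cell types, the tests, the threshold, the alternatives and the rule for naming genes were fixed before the data were examined. A list was described by how many tested members passed over all genes, and when adjusted over the list alone. It was also ranked against other genes with camera (limma 3.58.1), at a preset correlation of 0.01 and with an estimated one, with adjustment over the 21 lists with at least 3 tested members. Of the receptor list, 24 members did not pass the expression filter, for low counts or counts in too few libraries. The spellings Mrgprc11, Tafa4, Scn2a and Galr3 matched no symbol. Of these genes, Mrgprc11 was listed also as Mrgprx1 and tested, Tafa4 was listed also as Fam19a4 and did not pass the filter, and Scn2a stood in the table as Scn2a1, tested among all genes but not in its list. Named genes were the 3 genes behind the labels and the title, the 12 genes with the largest fitted difference in each direction among called genes with a mean log2 CPM of at least 3 and no overlap between groups, every called member of the NP3 and mediator receptor lists, and up to 4 called members with the smallest p of each other list, or its most abundant member where none was called. Predicted genes, pseudogenes and sex-linked genes were left out of the 12.

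Where a group had 0 counts of a gene, a floor of 3 counts over the group gave a lower bound of the fold. With 1 to 3 counts, the ratio was given with a 95% exact binomial interval. Single measures per library were compared by exact permutation. The analysis was tested on simulated data: in counts drawn for the 11828 genes of this comparison, 7% of 100 genes changed 2-fold and 42% of 100 genes changed 4-fold were recovered. Of 56 calls 7 were false, a larger share than the threshold of 0.05 sets, and 0 had the wrong sign. A 2-fold shift of the TRP channel list was found by camera (adjusted p = 4.96e-13), with 0 of the other lists called. Genes were drawn independently there, whereas correlations estimated in the data ran from −0.168 to 0.854 by list. The simulation therefore cannot show how often camera calls lists falsely at the preset correlation. In the simulation of single genes most differences of 2-fold were missed.

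Alternatives were other size factors (RLE), no filter, a stricter filter (CPM of at least 5 in 4 libraries), DESeq2 1.42.0, limma voom with sample quality weights, dispersion estimates without robustness, the replicate number as a block, the mean of the glial list as a covariate, thinning to the smallest library, and leaving out each library. Chosen after seeing the data were a term for libraries with Xist and no Y-linked counts, a fit of those 6 libraries alone and the removal of mitochondrially encoded genes. Also chosen then, for the direction of called genes, was a fit of the 4 libraries with at most 1 count each of the pituitary hormone genes Gh and Prl. The sex of the mice in each sample is not given in the sources used here, and the presence of Xist and Y-linked counts was read from the table.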

Results

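RNA sequencing was carried out on 2 populations of mouse dorsal root ganglion (DRG) neurons, the sensory neurons whose cell bodies lie beside the spinal cord. In Sst-IRES-Cre mice the Cre recombinase is made from the locus of Sst, which encodes the peptide somatostatin. In Trpv1-IRES-Cre mice it is made from the locus of Trpv1, which encodes the channel gated by heat and capsaicin. C57Bl/6 pups received, at postnatal day 2, an intraperitoneal injection of an adeno-associated virus whose fluorescent reporter is switched on by Cre. At 3 to 5 weeks of age, 150 to 250 fluorescent neurons per mouse were picked by hand from dissociated ganglia. The labels give 4 independent samples of each genotype, called the Sst and the Trpv1 libraries here. Total gene counts ran from 9021125 to 12153109 in the Sst libraries and from 7419027 to 9568508 in the Trpv1 libraries, and 14437 to 16917 genes held counts in each. These reads carried no molecular identifiers, so intervals and floors given for low counts cover counting error only.

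Several measures differed between libraries, and the sex signal was partly aligned with genotype. All 4 Sst libraries held counts of Xist, the RNA of the inactive X chromosome (4240 to 6598), and 0 counts of Y-linked genes. Trpv1 replicates 1 and 2 held 0 counts of Xist and 825 and 860 Y-linked counts, while Trpv1 replicates 3 and 4 held 12659 and 7994 counts of Xist and 0 Y-linked counts. Mitochondrially encoded protein genes took 4.31% ± 0.820 of the counts in the Sst libraries and 5.51% ± 2.35 in the Trpv1 libraries (SD, n = 4 each), with 9.04% in Trpv1 replicate 3. The pituitary hormone genes Gh and Prl held 937 and 3245 counts in Sst replicate 2, and between 1332 and 11494 counts in Trpv1 replicates 1, 2 and 3. The other 4 libraries held at most 1 count of either gene. Pomc, also in the neuropeptide list, held 1501 and 468 counts and Fshb 1014 and 87 in Trpv1 replicates 1 and 2. Tshb, another pituitary hormone gene, held 38, 11 and 1 counts in Sst replicates 1, 3 and 4. It held 16, 82 and 33 counts in Trpv1 replicates 1, 2 and 3, and 0 in Sst replicate 2 and Trpv1 replicate 4. Pituitary genes took 0.0472% to 0.192% of the counts in Sst replicate 2 and Trpv1 replicates 1, 2 and 3. Neither Gh nor Prl passed between genotypes in edgeR (Gh log2 fold change −4.22, adjusted p = 0.295, and Prl −3.05, adjusted p = 0.488). None of 6 library measures, among them depth, number of genes and mitochondrial share, separated the genotypes (exact permutation tests, two-sided, n = 4 each, p from 0.0857 to 0.971, adjusted p from 0.514 to 0.971). The smallest p that 4 against 4 libraries allow is 0.0286.

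The genotypes lay apart on the principal component with the most variance (27.9%), as the plot of principal components shows. Correlations of log2 CPM (counts scaled by library size) across the tested genes were 0.784 to 0.884 between Sst libraries, 0.782 to 0.837 between Trpv1 libraries and 0.735 to 0.821 between genotypes. Genes are not independent replicates, so these correlations describe the libraries only.

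**Figure D1:**
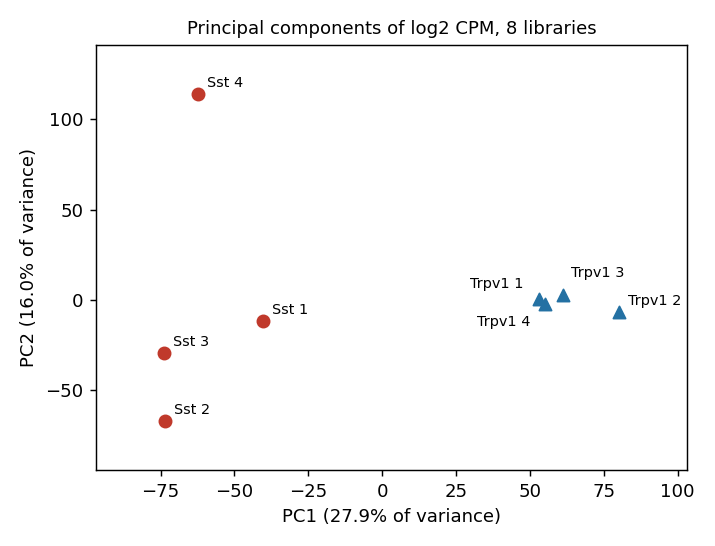
Principal components of log2 CPM (TMM-normalized, prior count 2) over the 11828 tested genes, 1 point per library, with the percentage of variance on each axis. Sst libraries (circles) all lie left of the Trpv1 libraries (triangles) on the horizontal axis, and Sst replicate 4 lies apart from the other Sst libraries on the vertical axis.

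Sst and Nppb, which encode somatostatin and natriuretic polypeptide b and mark the DRG neuron class known as NP3, had higher means in the Sst libraries, and Trpv1 had a higher mean in the Trpv1 libraries. None of the 3 genes passed the test across all genes. Sst (GRCm38 chromosome 16, 23889573 to 23890958, minus strand) stood at 198 ± 106 CPM in the Sst libraries and 94.2 ± 47.4 CPM in the Trpv1 libraries (SD, n = 4 each), a log2 fold change of 1.07 (SE 0.354, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0753). Nppb (chromosome 4, 147985788 to 147987205, plus strand) stood at 42.1 ± 19.3 and 18.9 ± 7.33 CPM, a log2 fold change of 1.15 (SE 0.442, edgeR adjusted p = 0.129). Trpv1 (chromosome 11, 73234292 to 73261242, plus strand) stood at 101 ± 69.2 and 195 ± 77.9 CPM, a log2 fold change of −0.95 (SE 0.348, edgeR adjusted p = 0.109). Transcripts of Sst, Nppb and Trpv1 were thus counted in both populations, and the labels, not these genes, define the groups. Leaving out single libraries changed the call: Sst passed without Sst replicate 2 (log2 fold change 1.35, adjusted p = 0.0166) or without Trpv1 replicate 4 (1.49, adjusted p = 0.0206), and Trpv1 passed without Sst replicate 4 (−1.55, edgeR adjusted p = 0.00307). Trpv1 also passed with limma voom and sample weights (−1.19, adjusted p = 0.0278). Both Sst and Trpv1 passed in edgeR with the replicate number as a block, with values given further below. Over all alternatives the adjusted p ran from 0.0166 to 0.415 for Sst, from 0.0934 to 0.388 for Nppb and from 0.00307 to 0.355 for Trpv1.

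The comparison asks how neurons picked by Sst-driven Cre differ from those picked by Trpv1-driven Cre. Of 11828 genes tested, 751 (6.35%) differed: 360 were higher in the Sst libraries and 391 in the Trpv1 libraries (edgeR quasi-likelihood test, adjusted p under 0.05). Of the 751 genes, 388 differed by more than 4-fold, and 646 had no overlap between the CPM values of the groups. Across all genes, 1317 (11.1%) had no overlap, where chance gives 2.86%. Without Sst replicate 1, Sst replicate 3 or Trpv1 replicate 3 the test called 500, 452 and 487 genes. With a term for the presence of Xist it called 435, and in the 6 libraries with Xist and no Y-linked counts 305. In the 4 libraries with at most 1 count each of Gh and Prl (3 Sst and 1 Trpv1), 1 of the 751 genes had the opposite sign.

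Among the 12 genes with the largest difference toward the Sst libraries were genes of receptors, transmitter transport and synapses. Sema5b, a semaphorin of axon guidance, stood at 41.3 ± 34.6 CPM in the Sst libraries and had 0 counts in all Trpv1 libraries. It was therefore at least 491-fold higher, taking a floor of 3 counts over the group (edgeR adjusted p = 0.000295), and without Sst replicate 3 at least 287-fold. Htr1d, a serotonin receptor gene, stood at a mean of 68.1 CPM against 1 count in the Trpv1 group, a ratio of 2387 (95% counting interval 428 to 94326; edgeR adjusted p = 1.57e-06). Slc17a7, a vesicular glutamate transporter, and Lypd1, a modulator of nicotinic receptors, also had 1 count each in the Trpv1 group, against 42.9 ± 13.2 and 35.3 ± 20.6 CPM in the Sst libraries. The counts of Htr1d, Slc17a7 and Lypd1 in the Trpv1 group all lay in Trpv1 replicate 3. Without that library their fitted log2 fold changes moved from 10.67, 10.00 and 9.70 to 12.37, 11.70 and 11.40. The Trpv1 group then held 0 counts of these genes, so the moved values measure no size of difference. The noncoding RNA gene Tbx3os2 was at least 222-fold and Ankrd34c at least 193-fold higher; whether reads were counted by strand is not given in the sources used here, so reads of Tbx3os2 cannot be told apart from any on the opposite strand. Baiap2l1 stood at 82.2 ± 16.7 against 0.117 ± 0.136 CPM, and the GABA receptor subunit gene Gabrb2 at 27.1 ± 4.62 against 0.186 ± 0.224 CPM. Cbln2, a synaptic organizer, Necab2, a neuronal calcium-binding protein, Epn3 and Tmem108 completed the set, with log2 fold changes of 7.50, 6.89, 7.22 and 6.50. The counts of Epn3 and Tmem108 in the Trpv1 group came from 1 library each. The fitted value was 10.54 for Epn3 without Trpv1 replicate 3 and 10.57 for Tmem108 without Trpv1 replicate 2. Those fits likewise left 0 counts of the gene in the Trpv1 group, so their values measure no size of difference. Fitted values also moved to 8.48 for Necab2 without Trpv1 replicate 1, to 8.30 for Gabrb2 (from 7.19) without Trpv1 replicate 2 and to 8.28 for Cbln2 without Trpv1 replicate 4. In the 6 libraries with Xist the calls of Ankrd34c, Epn3, Necab2 and Tmem108 were lost, with edgeR adjusted p just over 0.05 for Epn3 and from 0.0548 to 0.0699 for the others, the highest of any alternative for each gene.

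The 12 genes with the largest difference toward the Trpv1 libraries included peptides of nociceptors and their receptors. Gal, which encodes galanin, stood at 34.6 ± 15.3 CPM in the Trpv1 libraries and had 2 counts in the Sst group, a ratio of 718 (95% counting interval 198 to 5934). The galanin receptor gene Galr1 stood at 35.1 ± 12.3 CPM and also had 2 counts in the Sst group, a ratio of 710 (196 to 5870). Slc5a7, the choline transporter of cholinergic terminals, had a ratio of 560 (155 to 4633). Adcyap1, which encodes the peptide PACAP, stood at 233 ± 28.1 CPM in the Trpv1 libraries and 2.81 ± 2.23 CPM in the Sst libraries, a log2 fold change of −6.43 (SE 0.404, edgeR adjusted p = 1.78e-10). Chrnb4, a nicotinic receptor subunit gene, stood at 119 ± 34.3 against 1.02 ± 1.17 CPM, and Cacna1e, a voltage-gated calcium channel gene, at 197 ± 40.0 against 2.87 ± 3.69 CPM. The remaining genes, Gabrg3, Tnfaip8l3, Cartpt, Smr2, C1qtnf7 and Syt16, had log2 fold changes from −6.26 to −5.50. Several fitted values rested on Sst replicate 1. Without it those of Gal, Galr1 and Slc5a7 moved from −9.13, −9.14 and −8.80 to −11.35, −11.36 and −11.02. The Sst group then held 0 counts of these genes, so the moved values measure no size of difference. Also without Sst replicate 1, the fitted values of Gabrg3, Cartpt, Smr2 and Syt16 moved from −6.26, −5.83, −5.80 and −5.50 to −8.60, −8.44, −7.15 and −6.35. Those of Chrnb4 and Cacna1e moved from −6.95 and −6.12 to −7.57 and −7.55. Without Sst replicate 4, Tnfaip8l3 and C1qtnf7 moved from −6.00 and −5.59 to −7.06 and −6.26. Tnfaip8l3 was no longer called with voom and sample weights (adjusted p = 0.0915, the highest over its alternatives), nor was Smr2 (0.0873, likewise the highest). The call of Tnfaip8l3 also ended with a term for Xist (0.0682) and in the 6 libraries with Xist (0.0874).

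Markers of the NP3 class, which holds Nppb and Sst, were counted in both populations. Of 16 members tested, 6 were higher in the Sst libraries, 1 was lower and 9 did not pass (11 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 1.04. Il31ra, which encodes a subunit of the receptor for the itch cytokine interleukin-31, stood at 454 ± 115 CPM in the Sst and 157 ± 8.71 CPM in the Trpv1 libraries (log2 fold change 1.54, SE 0.216, edgeR adjusted p = 4.67e-05). Jak1, a kinase of cytokine receptors, stood at 2933 ± 604 and 1309 ± 102 CPM, and Npy2r, a neuropeptide Y receptor gene, at 391 ± 133 and 168 ± 26.9 CPM. The serotonin receptor genes Htr1f and Htr1a had log2 fold changes of 1.24 and 1.01. S1pr1, a receptor gene for sphingosine 1-phosphate, stood at 40.9 ± 26.7 and 11.8 ± 4.67 CPM (log2 fold change 1.81, edgeR adjusted p = 0.0320). Il6st, a shared signalling subunit of interleukin-6 family receptors, went the other way, at 996 ± 237 CPM in the Sst and 2422 ± 177 CPM in the Trpv1 libraries (−1.28). Osmr and Cysltr2 stood at 950 ± 431 and 348 ± 114 CPM against 575 ± 55.7 and 212 ± 102 CPM (edgeR adjusted p = 0.0568 and 0.138), and Nts, Stat3, Trpc6 and Plxnc1 lay between −0.21 and 0.17. S1pr1 and Htr1f entered the list from knowledge of this study, so their direction is not independent evidence, nor is the count adjusted over the list alone. In limma's camera test the list ranked higher than other genes (adjusted p = 2.99e-05), which did not hold with an estimated correlation (adjusted p = 0.339). The 6 higher members became 3 without Sst replicate 4, with voom and sample weights, with a term for Xist, or in the 6 libraries with Xist. The call of S1pr1 was lost without Sst replicates 1 or 4 or Trpv1 replicates 1, 3 or 4 (edgeR adjusted p from 0.0594 to 0.149), that of Htr1a without Sst replicate 4 or Trpv1 replicates 3 or 4 (0.0561 to 0.0836) and that of Htr1f without Sst replicate 4 (0.0567).

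Receptors for mediators that mast cells release went both ways. Of 60 listed genes 36 were tested; 6 were higher in the Sst libraries, 4 were lower and 26 did not pass (9 higher and 8 lower when adjusted over the list alone). The median log2 fold change was −0.18 and the mean 0.16, and camera gave an adjusted p of 0.645 toward lower ranks. Higher members were the serotonin receptors Htr1d, Htr1f and Htr1a, S1pr1, Il31ra and the prostaglandin F receptor gene Ptgfr, which stood at 12.2 ± 8.56 and 1.29 ± 0.913 CPM. Lower members were Il6st, the prostaglandin D receptor gene Ptgdr (5.69 ± 2.58 and 41.2 ± 9.07 CPM, log2 fold change −2.84, edgeR adjusted p = 0.000620), the prostacyclin receptor gene Ptgir (−1.57) and Htr1b (−4.94, and −7.00 without Sst replicate 2). Histamine receptor genes were low: Hrh1 stood at 9.85 ± 13.2 and 5.16 ± 3.49 CPM and Hrh2 at 8.66 ± 7.36 and 7.76 ± 1.68 CPM. Hrh4 had 0 counts in all 8 libraries and Hrh3 85 in total. S1pr1, Il31ra, Htr1f, Htr1a and Il6st are also NP3 members. The 6 higher members became 3 without Trpv1 replicate 3 or 4 and 2 with voom and sample weights, a term for Xist, or the 6 libraries with Xist. The call of Ptgfr was lost in 12 of 19 alternatives, among them the removal of any library except Sst replicate 4 (edgeR adjusted p from 0.0726 to 0.111), and that of Ptgir without Trpv1 replicate 1 (0.0578).

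Markers of peptidergic nociceptors were lower in the Sst libraries nearly throughout. Of 15 members tested, 12 were lower, 0 were higher and 3 did not pass (15 lower and 0 higher when adjusted over the list alone or at an unadjusted p under 0.05 in edgeR), with a median log2 fold change of −4.28. Calca, which encodes calcitonin gene-related peptide, stood at 37.8 ± 21.4 CPM in the Sst and 1198 ± 239 CPM in the Trpv1 libraries, 32.0-fold more in the latter (log2 fold change −5.00, SE 0.308, edgeR adjusted p = 1.78e-10). Tac1, the precursor gene of substance P, stood at 21.4 ± 9.58 and 411 ± 119 CPM (−4.28), and the receptor kinase gene Kit at 6.10 ± 5.03 and 184 ± 48.6 CPM (−4.89). Calca and its close paralog Calcb can share reads, so the division between them is uncertain. DESeq2 and limma voom called 0 members higher. The members that did not pass in edgeR were Oprm1, Gpx3 and Trpv1. The list ranked lower than other genes in camera (adjusted p = 3.41e-23), also with an estimated correlation (adjusted p = 0.00226). In the 6 libraries with Xist 8 members passed.

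Other classes of unmyelinated neurons differed gene by gene. Of 9 tested markers of the NP2 class, 2 were lower, 1 was higher and 6 did not pass (3 lower and 1 higher when adjusted over the list alone). Mrgpra3, an itch receptor gene activated by chloroquine, stood at 7.88 ± 5.55 CPM in the Sst and 208 ± 98.2 CPM in the Trpv1 libraries (log2 fold change −4.76, edgeR adjusted p = 1.36e-07), and Mrgprx1 at 6.65 ± 1.67 and 79.6 ± 33.0 CPM. Genes of the Mrgpr family resemble each other closely, so their counts are uncertain. Carhsp1 was higher (1.09), a call lost without any library except Sst replicate 2 or Trpv1 replicate 4 (adjusted p from 0.0567 to 0.114). The NP2 list ranked lower in camera (adjusted p = 0.0252), which did not hold with an estimated correlation (adjusted p = 0.208). Of 13 NP1 markers, 4 were lower (Ptgdr, Cd55, Slc16a12 and Adra2a), 1 was higher (Tmem45b, outside the rule for named genes and named after its value was seen) and 8 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.177, 0.394 with an estimated correlation, and 0.0467 at the preset correlation without Trpv1 replicate 1). Mrgprd, the receptor gene that names the class, stood at 14.7 ± 4.72 CPM in the Sst libraries and did not pass (log2 fold change 0.01, SE 0.549, edgeR adjusted p = 0.992). The calls of Cd55, Slc16a12 and Adra2a each ended without Sst replicate 3 (edgeR adjusted p = 0.0591, 0.0544 and 0.0629). Those of Cd55 and Adra2a also ended without Sst replicate 2 (0.0541 and 0.0506), that of Cd55 without Trpv1 replicate 3 (0.0583) and that of Adra2a without Trpv1 replicate 1 (0.0522). Without Sst replicate 1 the fitted values of Slc16a12 and Adra2a moved from −3.61 to −5.51 and from −5.07 to −9.34. The Sst group then held 0 counts of Adra2a, so its moved value measures no size of difference. Of 7 markers of cold-sensing and Th C-fibre neurons, 1 was higher and 6 did not pass (2 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.618). The higher gene was Piezo2, a mechanically gated channel gene, at 581 ± 153 and 270 ± 60.3 CPM, with an adjusted p of 0.0613 in the 6 libraries with Xist (range over all alternatives 8.46e-05 to 0.0613).

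Markers of myelinated, large-diameter neurons were higher in the Sst libraries. Of 23 members tested, 21 were higher, 0 were lower and 2 (Cntnap2 and Asic1) did not pass, with the same counts when adjusted over the list alone or at an unadjusted p under 0.05 in edgeR, and a median log2 fold change of 2.53. DESeq2 and limma voom also called 0 members lower. Ntrk2, which encodes the receptor TrkB, stood at 409 ± 64.8 CPM in the Sst and 70.8 ± 31.0 CPM in the Trpv1 libraries (log2 fold change 2.53, SE 0.288, edgeR adjusted p = 2.57e-06). Scn1a, a sodium channel gene, stood at 202 ± 64.8 and 11.1 ± 12.5 CPM (4.22, and 5.24 without Trpv1 replicate 3), Cntn1, an axonal adhesion molecule, at 356 ± 95.4 and 57.0 ± 20.4 CPM, and Ldhb, a lactate dehydrogenase gene, at 266 ± 123 and 34.8 ± 15.2 CPM. The heavy neurofilament gene Nefh stood at 943 ± 254 and 246 ± 87.7 CPM. The list ranked higher than other genes in camera (adjusted p = 1.22e-28), but with an estimated correlation the adjusted p was 0.0692. In the 6 libraries with Xist 12 members passed, and the list's median was 2.75.

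**Figure D2:**
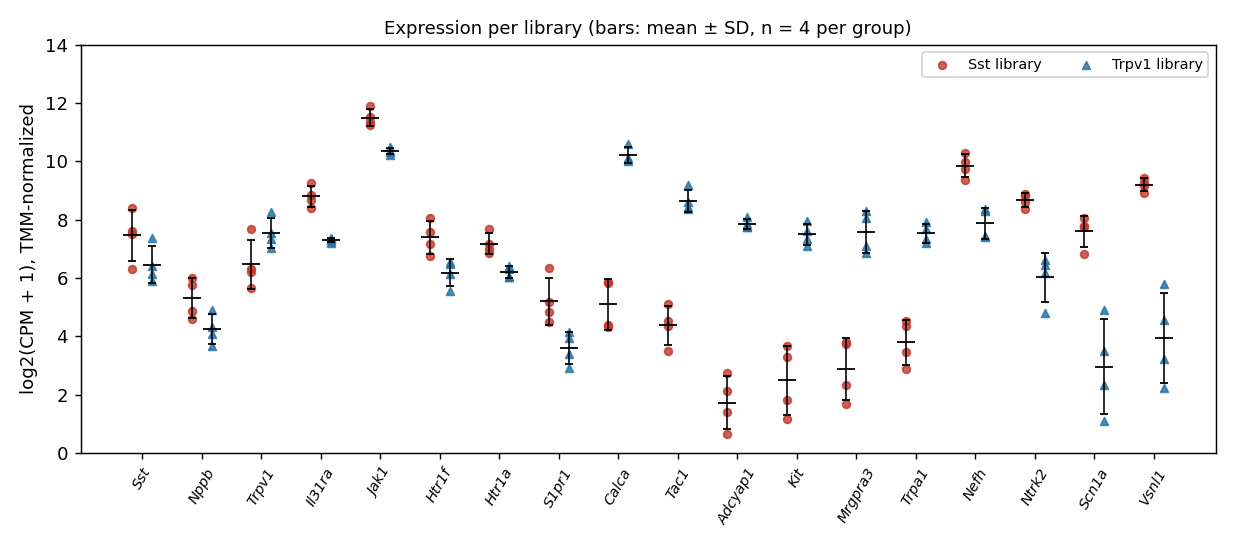
Expression in each library as log2(CPM + 1), TMM-normalized, of the genes behind the labels, NP3 markers, nociceptor and itch receptor genes and myelinated neuron markers; circles are Sst and triangles Trpv1 libraries, and bars give the mean and SD (n = 4 each). The ranges of the groups overlap for Sst, Nppb and Trpv1, whereas Calca stands at 37.8 and 1198 CPM and Scn1a at 202 and 11.1 CPM in the Sst and Trpv1 libraries.

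Ion channel genes of the same family lay on both sides. Of 16 TRP channel genes tested, 2 were higher in the Sst libraries, 3 were lower and 11 did not pass (4 higher and 5 lower when adjusted over the list alone). Trpa1, the channel gated by irritants, stood at 14.4 ± 7.44 and 188 ± 43.2 CPM (log2 fold change −3.70, edgeR adjusted p = 1.60e-07), and Trpm3, another heat-gated channel, at 37.9 ± 8.49 and 95.8 ± 8.27 CPM. Trpc4 had 1 count in the Sst group against 7.10 ± 2.01 CPM (ratio 289, 95% counting interval 51.4 to 11461). Its fitted value moved from −7.56 to −9.06 without Sst replicate 2. That fit left 0 counts of Trpc4 in the Sst group, so the moved value measures no size of difference. The calls of Trpm3 and Trpc4 were lost in the 6 libraries with Xist (adjusted p = 0.0856 and 0.0802, the highest over their alternatives). Trpm6 was higher (1.52), a call lost without any library except Sst replicates 2 or 3 (edgeR adjusted p from 0.0504 to 0.0893); the other higher gene, Trpm2 (1.40), was named after its value was seen. The median of the TRP list was 0.17 and its mean −0.53, and camera gave an adjusted p of 0.618 toward lower ranks. Of 24 voltage-gated sodium and calcium channel genes, 5 were higher, 3 were lower and 16 did not pass (7 and 4 when adjusted over the list alone; median −0.10, mean 0.26, camera adjusted p = 0.984). Scn8a stood at 350 and 85.6 CPM (log2 fold change 2.03, SE 0.243), and Cacna2d1, a target of gabapentin, at 141 ± 46.9 and 431 ± 87.4 CPM. Of 31 voltage-gated potassium channel genes, 12 were higher, 3 were lower and 16 did not pass (13 and 6 when adjusted over the list alone), with a median of 0.78. Kcnq3, a subunit of the M-current, stood at 183 ± 45.6 and 12.7 ± 11.3 CPM (3.90, and 4.66 without Trpv1 replicate 3), Kcna1 at 364 ± 130 and 69.7 ± 25.3 CPM, and Kcnh7 at 1266 ± 202 and 516 ± 97.7 CPM, while Kcnv1 stood at 1.32 ± 1.38 and 44.4 ± 18.6 CPM (−5.08, and −6.06 without Sst replicate 1). The potassium channel list ranked higher in camera (adjusted p = 0.00177), which did not hold with an estimated correlation (adjusted p = 0.0969). The 12 higher potassium channel genes became 6 without Sst replicate 3, Trpv1 replicate 1 or Trpv1 replicate 3.

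Of 14 neuropeptide genes tested, 6 were lower in the Sst libraries (Adcyap1, Calca, Tac1, Cartpt, Gal and Calcb, all also peptidergic markers), 0 were higher and 8 did not pass (7 lower and 3 higher when adjusted over the list alone). The median log2 fold change was −0.93 (camera adjusted p = 5.23e-05, and adjusted p = 0.104 with an estimated correlation). Toward higher values in the Sst libraries, 3 neuropeptide genes passed at an unadjusted p under 0.05 in edgeR, 1 in DESeq2 and 0 in limma voom. Of 16 genes of opioid, somatostatin, neuropeptide Y and other inhibitory receptors, 6 were lower, 2 were higher (Npy2r and Grm4) and 8 did not pass (7 and 2 when adjusted over the list alone). Npy1r stood at 2.66 ± 1.42 and 76.0 ± 66.2 CPM (log2 fold change −4.88, edgeR adjusted p = 1.16e-05, and −4.04 without Trpv1 replicate 4), and Grm4, a metabotropic glutamate receptor gene, at 27.7 ± 5.94 and 3.61 ± 1.25 CPM. The list ranked lower in camera (adjusted p = 0.0185), which did not hold with an estimated correlation (adjusted p = 0.149) or with libraries thinned to one depth (0.0664), and its 6 lower members became 3 without Sst replicate 2. Of 37 ionotropic receptor genes, 6 were higher, 6 were lower and 25 did not pass (9 and 8 when adjusted over the list alone; median −0.13, mean 0.07, camera adjusted p = 0.984 toward lower ranks). The GABA receptor subunit gene Gabrg3 stood at 0.715 and 55.0 CPM (−6.26, SE 0.770, and −8.60 without Sst replicate 1). The nicotinic subunit gene Chrna3 stood at 4.48 ± 6.26 and 144 ± 35.5 CPM (−5.09, and −6.67 without Sst replicate 2).

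**Figure D3:**
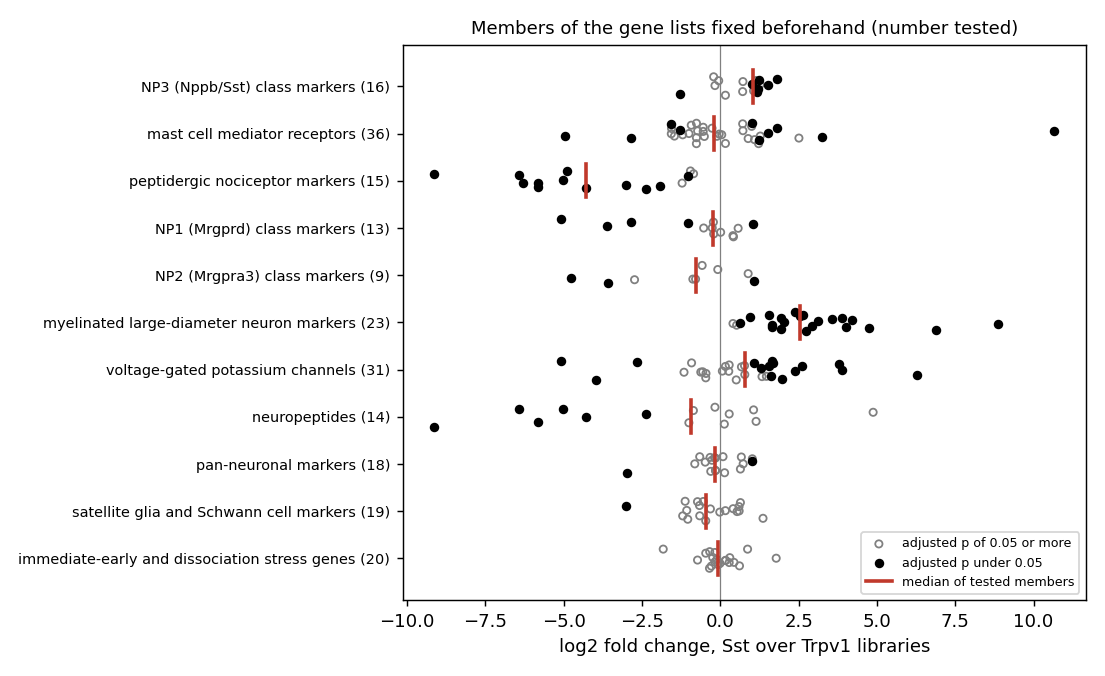
Log2 fold change, Sst over Trpv1 libraries, of each tested member of 11 gene lists, with the number tested in parentheses. Filled points passed an adjusted p of 0.05, open points did not, and vertical bars mark list medians, which run from −4.28 for peptidergic nociceptor markers to 2.53 for myelinated neuron markers.

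Few markers of other cell types passed the test. Of 18 pan-neuronal genes 1 was higher (Snap25, of the vesicle fusion machinery, 4052 ± 372 and 2000 ± 271 CPM), 1 was lower (Gap43, a growth cone protein, 47.1 ± 19.3 and 369 ± 73.4 CPM) and 16 did not pass (3 and 4 when adjusted over the list alone; camera adjusted p = 0.618). Of 19 satellite glia and Schwann cell genes 1 was lower and 18 did not pass (3 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.336). The lower gene, Gfra3, is also a peptidergic marker (13.2 ± 9.13 and 108 ± 27.6 CPM). The mean log2 CPM of the glial list, Gfra3 included, was 5.05 ± 0.198 and 5.33 ± 0.415 (SD, n = 4 each; exact permutation test, two-sided, p = 0.257). The glial covariate was this mean and so holds Gfra3 as well. Of 13 endothelial, mural and fibroblast genes 1 was higher (Rgs5, 547 ± 161 and 215 ± 83.8 CPM) and 12 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.444). The call of Rgs5 was lost with a term for Xist or in the 6 libraries with Xist (adjusted p = 0.0600 and 0.0957, range over all alternatives 1.33e-05 to 0.0957). No member of the leukocyte (3 tested, camera adjusted p = 0.618), red blood cell (3 tested, 0.984), immediate-early and stress (20 tested, 0.864), mitochondrially encoded (12 tested, 0.110) or sex-linked (4 tested, 0.110) lists passed in edgeR, over all genes or when adjusted over the list alone. At an unadjusted p under 0.05 in edgeR, 1 leukocyte gene and 2 immediate-early genes passed and 0 of the other 3 lists; DESeq2 called 2 immediate-early genes and limma voom 1 sex-linked gene, and both called 0 in the other lists. Camera called the mitochondrially encoded list lower without Sst replicate 4, Trpv1 replicate 1 or Trpv1 replicate 2 (adjusted p from 0.00932 to 0.0250), and the sex-linked list higher without Sst replicate 3 (0.0398) or Trpv1 replicate 3 (0.0358), all at the preset correlation. In the 8 libraries with an estimated correlation, camera gave an adjusted p = 0.738 for the mitochondrial and 0.365 for the sex-linked list. The Y-linked members Ddx3y, Eif2s3y, Kdm5d and Uty did not pass the expression filter, so the sex-linked results leave them out. Their counts lay in Trpv1 replicates 1 and 2 alone. Of 12 mast cell genes 2 were tested: Kit, also a peptidergic marker, was lower, and Mitf did not pass. Jun stood at 228 ± 65.5 and 244 ± 50.1 CPM, Hbb-bs at 6.54 ± 2.37 and 4.25 ± 2.06 CPM, Itgam at 2.58 ± 2.52 and 7.27 ± 8.29 CPM (−1.51, −2.22 without Sst replicate 4 and −0.25 without Trpv1 replicate 1), and mt-Co1 at 15592 ± 4220 and 17500 ± 6153 CPM.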

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

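In each group of 4 libraries, a value was singled out when its gap to the nearest other library, as a share of the group's range, exceeded Dixon's critical value for 4 values. This met 24 of 201 groups of values. Chance would give about 5% only for independent, normally distributed values, which these are not. Where all other libraries of a group hold no counts of a gene, any count in the remaining library is flagged. Several measures also overlap, such as mt-Co1 and the mitochondrial share, so the number flagged is no evidence of an excess. No explanation was tested for these single values, and all are in TMM-normalized CPM unless stated.

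Many lay in genes that were near 0 in the lower group. In Trpv1 replicate 3, Htr1d, Slc17a7 and Lypd1 each stood at 0.127 and Epn3 at 0.508, against 0 in the other Trpv1 libraries. In Trpv1 replicate 2, Tmem108 stood at 0.895 against 0. In Sst replicate 1, Galr1, Gal and Slc5a7 each stood at 0.199 and Adra2a at 0.996, against 0 in the other Sst libraries. Also in Sst replicate 1, Gabrg3 stood at 2.49 (others up to 0.371), Cartpt at 2.39 (others up to 0.327) and Slc16a12 at 3.29 (others up to 0.463). In Sst replicate 2, Trpc4 stood at 0.109 against 0.

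Among genes with more counts, Ptgir stood at 29.7 in Sst replicate 4 (others up to 17.7), and the potassium channel gene Kcna1 at 171 in the same library (others 416 to 452). Calca stood at 1553 in Trpv1 replicate 4 (others 1037 to 1109), and Npy1r at 175 in that library (others 32.9 to 51.4). Kcnv1 stood at 72.1 in Trpv1 replicate 3 (others 32.2 to 37.4).

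Trpv1 replicate 3 also stood apart in mitochondrial RNA. There mt-Co1 was at 26688 (others 13937 to 15247), mitochondrially encoded protein genes took 9.04% of counts (others 4.32% to 4.36%), and their mean log2 CPM was 9.59 (others 7.96 to 8.19). In the same library the mean log2 CPM of the neuropeptide list was 5.72 (others 5.85 to 5.87). In Trpv1 replicate 1 the mean log2 CPM of the NP2 list was 3.33 (others 4.39 to 4.49), and that of the leukocyte list, with 3 tested genes, was 3.33 (others 0.52 to 0.76).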

How the results depend on the processing

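The term for Xist, the 6 libraries with Xist, the table without mitochondrial genes and the 4 libraries with at most 1 count each of Gh and Prl were chosen after seeing the data. All other alternatives were set before. Of 75 named genes, the 67 that were called kept their direction under every alternative run on named genes, and 47 kept their call under all of them. None of the 751 calls that an alternative tested had the opposite sign there, except 1 in the 4 libraries with at most 1 count each of Gh and Prl. The stricter filter tested 632 of the 751, thinning 742 and the others all. These fits share libraries with the fit that chose the calls, so a kept sign is no independent evidence. Other size factors, filters, DESeq2 (902 calls, with no adjusted p for 568 genes), dispersion without robustness, thinning to 7419027 counts (782 calls) and removal of mitochondrial genes kept the count of calls within 1.5 times of 751. The median log2 fold change over all genes was 0.01 with TMM and −0.01 with RLE. Where no cause follows from the alternative's construction, the cause of a change was not tested.

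Leaving out 1 library gave 452 to 747 called genes, with 222 to 411 higher in Sst and 222 to 347 higher in Trpv1. Higher members ran from 3 to 7 in the NP3 list and from 3 to 6 in the receptor list. With a term for Xist 435 genes were called (168 higher in Sst), and in the 6 libraries with Xist 305 (122 and 183 higher in Sst and Trpv1). Any 2 Trpv1 libraries against the 4 Sst libraries gave 282 to 391 calls, so fewer libraries alone bring counts of that size. In the 6 libraries 12 myelinated members were higher. With the term for Xist, in the 6 libraries or with voom and sample weights, 3 NP3 members and 2 receptors were higher. In the 4 libraries without pituitary counts 52 genes were called (15 higher in Sst, 37 in Trpv1). These included 0 NP3 members in either direction, 1 receptor higher and 0 lower, 4 myelinated members higher and 6 peptidergic members lower, with 1 Trpv1 library left.

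With the replicate number as a block, 572 genes were called. The numbers did not meet the rule set for pairing samples: deviations of same-numbered samples correlated from −0.030 to 0.032, where every pair needed over 0.1. Of the samples, 2 lay closest to their own number. This does not exclude an effect of the picking session. With the block, Sst passed (log2 fold change 1.02, adjusted p = 0.0369) and so did Trpv1 (−1.07, adjusted p = 0.0305). Leaving out 1 library, log2 fold changes ran from 0.69 to 1.49 for Sst and from −1.55 to −0.63 for Trpv1. Voom with sample weights gave −1.19 for Trpv1 (adjusted p = 0.0278).

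Single genes that turned direction were not called in the edgeR fit of all libraries with group as the sole term. Xist was called with its direction kept under 2 of its 20 alternatives. Jun (−0.10) turned to 0.0595 with the glial covariate, 0.16 with the term for Xist and 0.18 in the 6 libraries, and ran from −0.30 to 0.0404 with 1 library left out. Xist itself (−0.29) turned to 0.35 with the glial covariate, 2.06 with the block and 6.41 with voom (adjusted p = 0.0357, range over its alternatives 0.00379 to 0.990), and ran from −0.69 to 0.82 with 1 library left out, where 2 of 4 Trpv1 libraries hold none. mt-Co1 ran from −0.27 to 0.11 with 1 library left out, and from −0.39 to 0.11 over all alternatives.

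In camera (adjusted p, all at the preset correlation), the mitochondrially encoded list passed toward lower with the glial covariate (0.0132), voom (0.0393), the block (0.0226), the term for Xist (0.000132) and the 6 libraries (0.000995), and ran from 0.00932 to 0.828, with the direction turned, when 1 library was left out. With an estimated correlation in the 8 libraries its adjusted p was 0.738. The vascular and fibroblast list passed toward higher with the glial covariate (0.0146), the term for Xist (0.0176) and the 6 libraries (0.0261), and ran from 0.147 to 0.987, turned. Its adjusted p with an estimated correlation was also 0.738. NP1 passed with the glial covariate (0.0476) and ran from 0.0467 to 0.404, and with an estimated correlation its adjusted p was 0.394. The inhibitory receptor list was lost with thinning (0.0664).

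Lists that turned direction without a call were these. The mediator receptors turned with DESeq2 (0.929) and the block (0.986). The ionotropic list turned with DESeq2 (0.396), voom (0.953), no filter (0.840), the block (0.986) and the stricter filter (0.984), and ran from 0.651 to 0.987 by library. The sodium and calcium channels turned with DESeq2 (0.396), no filter (0.840), the block (0.685) and thinning (0.991), and ran from 0.826 to 0.987. The glial list turned with its own covariate (0.904), the 6 libraries (0.882) and the term for Xist (0.881). The stress list turned with voom (0.953) and ran from 0.471 to 0.900. Red blood cell genes turned with the term for Xist (0.881) and thinning (0.991), and ran from 0.482 to 0.881. Sex-linked genes turned with no filter (0.510), the 6 libraries (0.619) and the term for Xist (0.557), and ran from 0.0358 to 0.302.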

Other observations

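Families outside the fixed lists were gathered after the calls had been seen, so their counts describe these data and are no evidence of enrichment. Of 46 genes of mitochondrial respiration and glycolysis, 18 were higher in the Sst libraries, 0 were lower and 28 did not pass (median log2 fold change 0.77). Atp5b, an ATP synthase subunit gene, stood at 1606 and 857 CPM in the Sst and Trpv1 libraries (log2 fold change 0.91, SE 0.173), and the neuronal enolase gene Eno2 at 345 and 151 CPM (1.19, SE 0.244). Of 13 sodium and calcium pump genes 6 were higher and 2 lower. The calcium pump gene Atp2b2 stood at 317 and 15.4 CPM (4.36, SE 0.303, edgeR adjusted p = 1.73e-09), whereas Atp2b4 stood at 74.6 and 343 CPM (−2.19, SE 0.267). The group means are over 4 libraries each.

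Of 34 transcription factor genes of sensory neuron classes, 9 were higher in the Sst libraries, 5 were lower and 20 did not pass. Tbx3 stood at 50.4 and 2.40 CPM (4.38, SE 0.611), Esrrg at 65.0 and 3.86 CPM (4.11, SE 0.509) and Shox2 at 18.1 and 0.979 CPM. Skor2 and Runx3 stood at 14.5 and 6.12 CPM, with 0 counts in all Trpv1 libraries. Zeb2 stood at 51.7 and 359 CPM (−2.80, SE 0.259, edgeR adjusted p = 1.24e-07). Of 22 neurotrophic receptor genes 10 were lower, among them Ngfr (291 and 666 CPM), and 2 were higher, Ntrk2 and Ntrk3. Of 30 synaptic genes 9 were higher and 7 lower: Vamp1 stood at 198 and 50.3 CPM, and Syt4 at 188 and 503 CPM.

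Tests chosen after the result was seen were those of sex, of several neuron classes, of free RNA and of heterogeneity over all NP3 members, and all tests of pituitary RNA; those of length and GC, of 5 NP3 genes and of the splits were chosen before.

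The myelinated list had a median log2 fold change of 2.53 toward the Sst libraries. Sex does not account for all of it, since in the 6 libraries with Xist and no Y-linked counts the median was 2.75 (23 of 23 members above 0), nor do length and GC, since after removal of their trend, which held 3.84% of the variance, it was 2.53. A candidate explanation is that the picked Sst cells held more than 1 neuron class, whether labelled by Cre in these mice or picked with them. Sst replicate 4 was above the other Sst libraries in 16 of 16 NP3 members (median 0.66) and below them in 21 of 23 myelinated members (median −0.65), a difference of 1.31. This rests on 1 library noticed after the fact, and classes in pools cannot be told apart from co-expression in single cells, so it stays open, as does a difference between genotypes in what the cells themselves express.

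Of 16 NP3 markers tested, 6 were higher and 1 was lower in edgeR (median 1.04, camera adjusted p = 0.339 with an estimated correlation), and their median level in the Trpv1 libraries was 48.7% of that in the Sst libraries. If NP3 cells were among the picked Trpv1 cells, genes of the class should share 1 ratio, and Nppb, Sst, Il31ra, Cysltr2 and Htr1f, named for this before the data were seen, had a pooled level of 43.4% (36.3% to 51.9%); Htr1f had entered the list from knowledge of this study. Cochran's Q gave a heterogeneity p of 0.239 over these genes but 2.25e-35 over all tested members, among them Il6st at −1.28, Nts at −0.17 and Plxnc1 at 0.17; members need not be restricted to the class and genes share libraries, so this cannot be told apart. Free RNA from the same ganglia should reach both groups alike. The NP3 share in Trpv1 libraries was 9.47 times the peptidergic share in Sst libraries (interval 1.58 to 31.2 from a bootstrap over list members). List members share libraries, so the interval does not measure the spread between libraries. NP3 members not restricted to the class would also raise the NP3 share. The interval includes ratios under 3, the bound set for this test, so a part from free RNA cannot be told apart.

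RNA of the pituitary hormone genes Gh and Prl stood at 937 counts or more each in 4 libraries, of both genotypes. Tshb did not follow them: it held 38 and 11 counts in Sst replicates 1 and 3 and 0 in Sst replicate 2. The candidate sources are hypotheses, and hand-picking of fluorescent cells would be expected to leave such cells out. Gh held 937, 9044, 5487 and 1332 counts and Prl 3245, 5122, 6906 and 11494 in Sst replicate 2 and Trpv1 replicates 1, 2 and 3, with Pou1f1 at 63, 193, 122 and 39. If the picked neurons of a genotype generally expressed these genes, all its libraries should hold them, but 4 libraries held at most 1 count of either. Expression in only some pools was not tested. A single pool of RNA would be expected to keep 1 ratio of Gh to Prl, but this differed 15.2-fold between libraries (0.116 to 1.77). That ratio was judged against counting error alone, and amplification adds spread beyond it. The ratio was 2.75 times higher in the lowest library with Y-linked counts than in the highest with Xist, which is consistent with RNA from the animals' own pituitaries, but 4 libraries allow no p under 0.333, so this stays open.

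The 8 libraries can be split into 4 and 4 in 35 ways. All splits but the real one mix both genotypes on each side, so a real difference between genotypes would itself lower their calls. The real split gave 751 called genes and the highest other split 1. With 1 of 35 splits as large, the smallest share these splits allow, chance is unlikely for that count but not excluded. The other splits therefore had almost no calls to give to any list, so the counts of called members restate that total and say nothing more about the lists: NP3 7 in the real split and at most 0 in the others, mediator receptors 10 and 0, peptidergic 12 and 0, myelinated 21 and 0, each with 1 of 35 splits as large. For the number of lists called by camera chance cannot be excluded: the real split gave 7 lists, the highest other split 8, and 3 of 35 splits gave as many. The other splits that reached this number kept 3 libraries of a genotype together and so part of the real difference, while splits with 2 libraries of each genotype on either side gave at most 5 lists.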
